A study of Mus musculus with 16 samples.

How the data were processed

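Left ventricular RNA of 16 mice was sequenced as poly(A)-selected, strand-marked libraries, 4 for each combination of diet (CD, low-fat control; HFHS, high fat and high sucrose) and drug (none or ertugliflozin), per the labels' protocols. The submitters took 4 animals per group from a larger number and called them representative, so the spread between libraries is the spread between those animals.

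The deposited count table holds whole read counts for 53764 Ensembl genes, not normalized. Per the submitters' processing notes the tools were STAR 2.6.0c, featureCounts from Subread 1.6.2, FastQC 0.11.7 and DESeq2 1.22.1, with the mm10 build; the annotation, strand setting and handling of reads that map to several places are not given in the sources used here. The authors also deposited a table of regularized log2 values, used only as an alternative input. Of the IDs in the count table, 53583 were given a symbol from GENCODE M21 (GRCm38), which is also the source of the coordinates, and 181 were not. The latter took 0.018% to 0.022% of counts. The table held 0 mitochondrially encoded genes, so the list of 15 such transcripts was not tested. Totals were 14637669 to 21452212 counts per library. Library pairs within groups differed by a chi-square per degree of freedom of 3.23 to 16.3, so each library was counted as its own replicate.

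The counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr on the 4 groups, TMM factors, 1 fit over all 16 libraries with a mean per group, robust quasi-likelihood dispersions and glmQLFTest, with Benjamini-Hochberg adjustment over 15841 genes (15 without a symbol) and a threshold of 0.05. The drug effect was tested on each diet and averaged, the diet effect with and without drug, and the difference of the drug effects as an interaction. SE values of edgeR log2 fold changes were not taken from the fit. They are the size of the log2 fold change divided by the square root of the test's F statistic. CPM values (counts scaled by library total and TMM factor) are given as mean ± SD of 4 libraries.

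Lists of genes of heart metabolism, remodelling, stress and cell type markers were tested with camera on voom values (limma 3.58.1) at a preset correlation of 0.01, with the estimated correlation beside it and fry as a test of the list on its own. Of 52 lists 48 had at least 5 tested members. The others were the mitochondrially encoded transcripts (0 of 15 tested), T and NK cell markers (3 of 20), platelet markers (4 of 11) and lung and thymus markers (2 of 14). Members were counted as risen or fallen by edgeR over all genes and adjusted over the list alone. Reactome sets of 15 to 300 tested genes came with fgsea 1.28.0, and 13342 of the 15841 genes had 1 Entrez ID. A library's score for a list is the mean of its members' log2 CPM (prior count 2), centred over the 16 libraries.

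Groups, contrasts, lists and alternatives were fixed before the data were examined, as was the rule for named genes. For diet without drug and the drug on each diet it took the 7 largest rises, 7 largest falls and 10 smallest adjusted p among genes past the threshold with a mean of at least 1 CPM, up to 4 members of each called list, and the 10 smallest p where fewer than 10 genes passed. For the other contrasts it took the 5 smallest adjusted p, and it added 17 preset genes of transport, ketone use and remodelling. Where more than 30 genes resulted those of the largest p were left out, apart from Cilp2, the largest fall, and some preset genes. Some genes that the rule takes are not reported here. Genes known only by a model name were skipped. Rpl18 follows from its list, and values of a named gene in a further contrast are given for comparison.

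Chosen after the data were seen were the diet effect averaged over both drug arms, valve and atrial scores as covariates, a correction for gene length and GC content (lowess per library, span 0.3), leaving out CD untreated replicates 2 and 3, the permutation of library scores and lists that divide the interferon genes. Alternatives fixed earlier were RLE and upper-quartile scaling, no filter and a stricter one of 1 CPM, DESeq2 1.42.0, limma-voom with sample weights, limma on the deposited log2 values, the replicate number as a block, a fit of only the groups compared, and leaving out each library.

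The scripts were tested on simulated counts drawn from the real means and library sizes, with 66 or 67 genes changed at each of 3 sizes. The complex I subunits were shifted as a list as well, and each gene was drawn independently of the others. For diet without drug the edgeR test recovered 93.9% of 2-fold, 59.7% of 1.5-fold and 29.9% of 1.25-fold changes, with 3 false calls. For the drug on CD it recovered 89.4%, 68.7% and 25.4% with 9 false calls, and for diet with drug 89.4%, 53.7% and 40.3% with 3. Effects under about 1.25-fold are therefore mostly out of reach of single-gene tests at this depth and n. Counts are uncertain for close copies (Tgtp1 and Tgtp2, Acot1 and Acot2, Hspa1a and Hspa1b) and for Igtp and Irgm2, which overlap on 1 strand. Psmb9 and Tap1 overlap on opposite strands, and the strand setting is not known. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Nothing was excluded from the 16 libraries in the main comparisons. Dixon's ratio was read against 0.829.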

Results

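Messenger RNA was measured by bulk sequencing in left ventricle from male C57BL/6J mice that started a diet at 8 weeks of age and stayed on it for 4 months. The control diet (CD) was low in fat, and the other diet was high in fat and sucrose (HFHS). Each diet was given alone or with ertugliflozin, an inhibitor of the renal glucose transporter SGLT2, mixed in at 0.5 mg per g. Each of the 4 groups had 4 libraries, 16 in all, chosen by the submitters from a larger set of animals as representative. The deposited gene counts summed to 15897779 to 18701291 per library for CD untreated, 18278761 to 20293743 for CD ertugliflozin, 14637669 to 18745934 for HFHS untreated and 16554399 to 21452212 for HFHS ertugliflozin. The 10 most abundant genes took 11.4% to 13.1% of counts. Expression was compared for 15841 genes, with a common biological coefficient of variation of 0.0947. The first 3 principal components held 19%, 13.1% and 9.98% of the variance.

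The first comparison asked what the HFHS diet did to the heart without drug. Genes of fatty acid use were higher on HFHS. Pdk4, a kinase that shuts off pyruvate dehydrogenase, rose from 524 ± 97.5 to 1409 ± 407 counts scaled by library size (CPM, mean ± SD, n = 4 per group), a log2 fold change of 1.43 ± 0.24 (SE, edgeR adjusted p = 0.0106). Acot2, a mitochondrial acyl-CoA thioesterase, rose from 119 ± 6.62 to 207 ± 27 CPM, by 0.80 ± 0.08 (edgeR adjusted p = 5.80e-05), and the fatty acid transporter Cd36 rose from 2611 ± 196 to 3457 ± 199 CPM, by 0.41 ± 0.06. The lipid droplet protein Plin2 (0.43 ± 0.06), the acyltransferase Gpam of triglyceride synthesis (0.53 ± 0.07), the carnitine palmitoyltransferase Cpt1a (0.41 ± 0.08) and the oxidation enzymes Decr1 (0.47 ± 0.07), Ech1 (0.41 ± 0.06) and Etfdh (0.29 ± 0.05) rose too. Oxct1, which commits ketone bodies to oxidation, fell by 0.35 (SE 0.05, edgeR adjusted p = 0.00138). Bdh1, which interconverts the main ketone bodies, was at −0.46 ± 0.29 and did not pass (edgeR adjusted p = 0.465). Angptl4, an inhibitor of lipoprotein lipase, stood at 2.08 ± 0.51 and did not pass (edgeR adjusted p = 0.0599), though it passed without HFHS untreated replicate 1. In GRCm38, Acot2 (ENSMUSG00000021226) lies on chromosome 12 from 83987861 to 83993873, Pdk4 (ENSMUSG00000019577) on chromosome 6 from 5483351 to 5496309, and Cd36 (ENSMUSG00000002944) on chromosome 5 from 17781690 to 17888801.

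Other genes with large rises were Chrna2, a nicotinic receptor subunit, at 1.67 ± 0.16 (edgeR adjusted p = 5.80e-05), Aldh1a2, an enzyme of retinoic acid synthesis, at 1.05 ± 0.20, Egln3, a prolyl hydroxylase that acts on hypoxia-inducible factors, at 1.03 ± 0.12, and Mthfd2, a mitochondrial enzyme of folate metabolism, at 1.00 ± 0.18. Btnl9 rose by 0.86 ± 0.10, the transcription factor Tshz1 by 0.55 ± 0.06 and the membrane repair protein Dysf by 0.44 ± 0.06. Acot1 rose by 0.91 ± 0.17, but Acot1 and Acot2 are close paralogs whose counts are uncertain, and the call of Acot1 ended without CD untreated replicate 1. Among falls, the complement component C7 changed by −1.43 ± 0.21 (27.1 ± 5.76 to 10 ± 2.44 CPM, SD, n = 4 per group), the collagen gene Col11a2 by −1.67 ± 0.26 and Zfp185 by −1.33 ± 0.24. Cilp2, a cartilage matrix gene, changed by −3.57 ± 0.84 from 3.57 ± 2.17 to 0.291 ± 0.331 CPM (edgeR adjusted p = 0.0468). Its call ended without any 1 of the 8 libraries compared except CD untreated replicate 4. Nppa (−1.14 ± 0.44), Myh7 (−0.02 ± 0.48), Ucp3 (1.07 ± 0.44) and the glucose transporter Slc5a1 (−1.09 ± 0.35), the gene of SGLT1, did not pass. Slc5a2, the gene of the drug's target, had 0 to 3 counts per library and was below the filter.

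In total 327 genes changed, 229 higher and 98 lower on HFHS, by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (2608 had an unadjusted p under 0.05). DESeq2 gave 593 and limma-voom with sample weights 743. The count depended on single libraries. It was 846 without HFHS untreated replicate 1, and 133, 176 and 186 without replicates 2, 3 and 4 of that group. It was 189, 150 and 191 without CD untreated replicates 1, 2 and 3. With marker scores of heart valve and atrium as covariates, chosen after the data were seen, it was 0, while 326 of the 327 kept their sign, the median size went from 0.35 to 0.32 on the log2 scale and the median error from 0.07 to 0.1. The 327 were selected in the same libraries for effects large against their error, so kept signs are no separate support. Without CD untreated replicates 2 and 3, which had the highest valve marker scores, the count was 97, of which 72 were among the 327. Pdk4, Mthfd2, Col11a2, Zfp185, Etfdh, Cpt1a, Kdr, Acot1 and Cdh5 then no longer passed.

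Gene lists fixed before the data were examined were then tested with camera at a preset correlation. Of 22 tested PPAR target genes, 13 rose and 0 fell over all genes, and 17 rose and 1 fell adjusted over the list alone (median log2 fold change 0.39, camera adjusted p = 7.27e-20, adjusted p = 0.03 with an estimated correlation). That was the only list of 14 past the threshold that held with an estimated correlation. Fry, the test of a list on its own, called 2 lists, PPAR targets (fry adjusted p = 2.0e-04) and mitochondrial fatty acid oxidation (fry adjusted p = 0.022). Of 20 mitochondrial fatty acid oxidation genes, 8 rose, and 16 rose and 1 fell adjusted over the list alone (median 0.21, camera adjusted p = 7.15e-13, adjusted p = 0.68 with an estimated correlation). The respiratory chain was slightly lower. The median was −0.078 for 36 complex I subunits (adjusted p = 0.77 with an estimated correlation), −0.099 for 23 subunits of complexes III and IV (adjusted p = 0.71 with an estimated correlation) and −0.11 for 15 ATP synthase subunits (adjusted p = 0.71 with an estimated correlation), with 0 of these genes past edgeR's threshold over all genes and 0, 2 and 3 fallen adjusted over the list alone. Of 19 genes of branched-chain amino acid catabolism, 2 fell and 3 fell adjusted over the list alone (median −0.11, adjusted p = 0.76 with an estimated correlation): Bckdhb, a subunit of the dehydrogenase that commits these acids to breakdown, by −0.49 ± 0.07, and the acyl-CoA dehydrogenase Acadsb by −0.22 ± 0.05. The call of Acadsb ended without CD untreated replicates 1, 2 or 4 or HFHS untreated replicates 2 or 4, each left out alone.

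Lists of other cell types also moved. Of 20 endothelial markers 2 rose, and 8 rose adjusted over the list alone (median 0.17, camera adjusted p = 1.23e-06, adjusted p = 0.7 with an estimated correlation). These were Kdr, a receptor for vascular endothelial growth factor, at 0.46 ± 0.07, and Cdh5, the cadherin of endothelial junctions, at 0.35 ± 0.07, whose call ended without CD untreated replicate 2 or HFHS untreated replicate 2. Valve and cartilage markers were lower in all 10 tested members (median −2.9, 1 fallen, 9 fallen adjusted over the list alone, adjusted p = 0.7 with an estimated correlation). Atrial cardiomyocyte markers were lower in 12 of 13 (median −0.49, 0 fallen, 5 fallen adjusted over the list alone, adjusted p = 0.71 with an estimated correlation). The mean valve score was 1.5 ± 0.94 in CD untreated and −0.94 ± 0.72 in HFHS untreated (log2, SD, n = 4 per group), with CD untreated replicates 2 and 3 at 2.3 and 2.2. The atrial score was 1.1 ± 0.91 and −0.43 ± 0.52, with CD untreated replicate 1 at 2.3. The fall of Cilp2 went with these scores. Col11a2 fell with them here but was also lower on HFHS among treated animals, at 3.21 ± 0.553 CPM on CD and 1.97 ± 0.451 on HFHS. There the mean valve score went up, from −0.49 to −0.036, and the mean atrial score down, from −0.18 to −0.47. Sarcomere genes had a median of −0.1 (0 of 22 fallen, 5 adjusted over the list alone, adjusted p = 0.7 with an estimated correlation) and lost the preset-correlation call without HFHS untreated replicate 1. Cytosolic ribosomal proteins had a median of −0.082 (1 of 41 fallen, Rpl18, 1 adjusted over the list alone, adjusted p = 0.77 with an estimated correlation). Heat shock genes (−0.15), cell cycle genes (0.2) and B and plasma cell markers (0.59) passed at the preset correlation with 0 members changed by edgeR and adjusted p of 0.77, 0.77 and 0.76 with an estimated correlation.

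**Figure D1:**
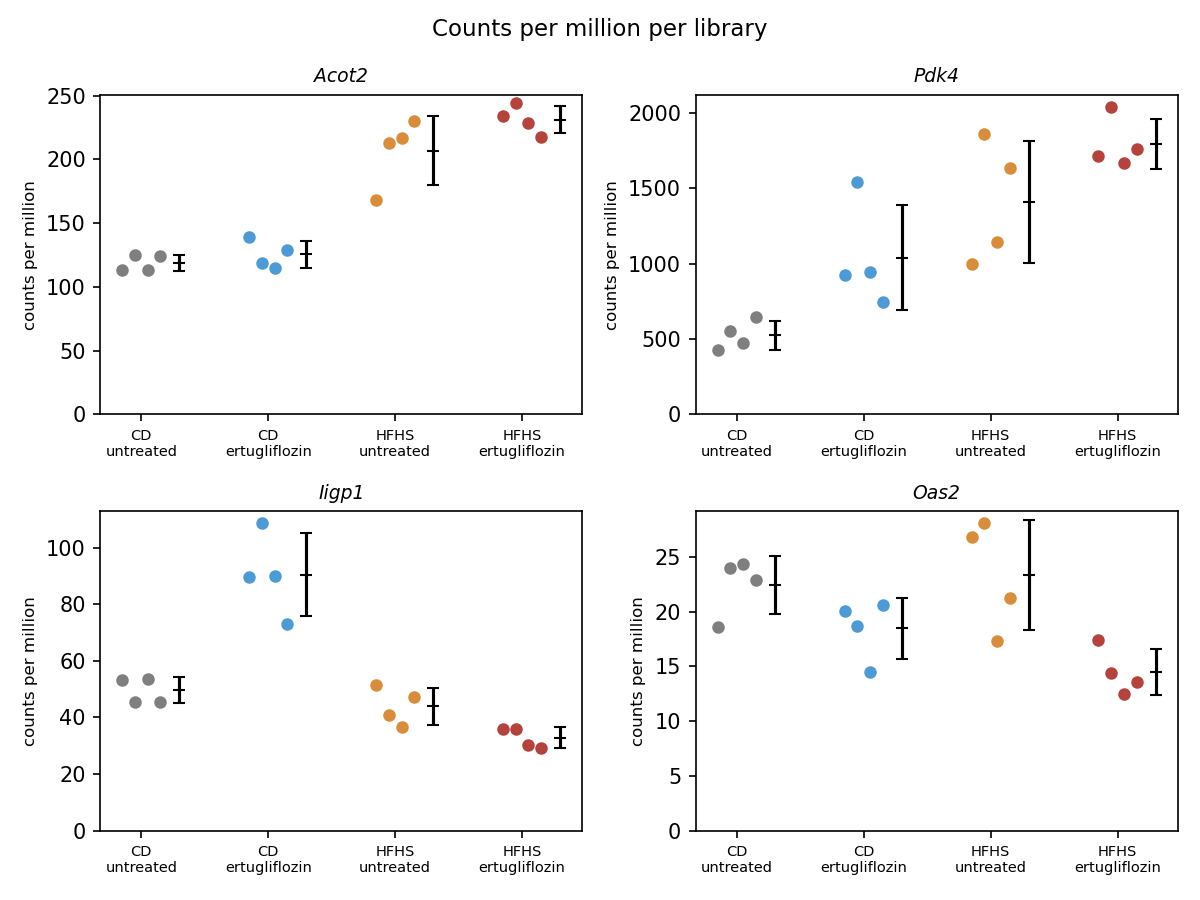
CPM of Acot2, Pdk4, Iigp1 and Oas2 in each of the 16 libraries by group, with the mean and SD of 4 libraries drawn as a line and bars. Acot2 averaged 119 in CD untreated and 207 in HFHS untreated, and Iigp1 averaged 90.5 in CD ertugliflozin and 32.8 in HFHS ertugliflozin.

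The same diet comparison among treated animals gave a similar set of metabolic genes, and lower interferon-inducible genes in HFHS ertugliflozin than in CD ertugliflozin. The interferon difference was not seen without drug. There 18 of 28 interferon response genes were higher on HFHS (median 0.061, camera adjusted p = 0.34). Against CD ertugliflozin, HFHS ertugliflozin hearts had higher Acot2 (0.88 ± 0.08, SE, edgeR adjusted p = 1.15e-05), Chrna2 (1.82 ± 0.15) and Fbxo21, an F-box protein (0.59 ± 0.06). Pdk4 stood at 0.79 ± 0.24 and did not pass (edgeR adjusted p = 0.0912). Oxct1 changed by −0.45 ± 0.05 and Bckdhb by −0.54 ± 0.06. The interferon-inducible GTPases Tgtp2 and Iigp1 changed by −1.55 ± 0.15 and −1.46 ± 0.12 (n = 4 per group, edgeR adjusted p = 1.15e-05 for both). Of 28 interferon response genes, 10 fell over all genes, 24 fell adjusted over the list alone and 28 were lower (median −0.46, camera adjusted p = 1.55e-19, adjusted p = 0.34 with an estimated correlation). Macrophage markers were lower with them in 19 of 20 (median −0.27, 7 fallen adjusted over the list alone, adjusted p = 0.73 with an estimated correlation), as were erythroid markers in 9 of 9 (median −0.33, 0 adjusted over the list alone, adjusted p = 0.66 with an estimated correlation). Of 20 fatty acid oxidation genes 16 rose, and 16 rose and 1 fell adjusted over the list alone (median 0.28, adjusted p = 0.34 with an estimated correlation). Among PPAR targets 12 of 22 rose and 1 fell, and 13 rose and 2 fell adjusted over the list alone (median 0.32, adjusted p = 0.096 with an estimated correlation). Of 38 extracellular matrix genes 4 rose, and 12 rose adjusted over the list alone (median 0.39, adjusted p = 0.66 with an estimated correlation). Fibroblast markers moved with them: 2 of 19 rose, and 3 rose adjusted over the list alone (median 0.25, camera adjusted p = 0.0102, adjusted p = 0.79 with an estimated correlation). Of 19 genes of branched-chain amino acid catabolism 6 fell, and 10 fell adjusted over the list alone (median −0.15, adjusted p = 0.66 with an estimated correlation).

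In total 584 genes changed with diet among treated animals, 341 higher and 243 lower (edgeR, 2937 at an unadjusted p under 0.05). Camera called 15 of 48 lists and 0 with an estimated correlation, and fry, which asks whether a list moves one way on balance, called 4. DESeq2 gave 891 genes. Without HFHS ertugliflozin replicates 1, 2, 3 and 4 the count was 287, 303, 336 and 367, and without CD ertugliflozin replicates 2 and 3 it was 389 and 359. With upper-quartile scaling the split was 290 higher and 302 lower. The diet effects with and without drug share no library. Of 229 genes higher on HFHS without drug and 341 with drug, 125 were shared, where independent lists would share 4.93. Of 98 and 243 lower genes, 43 were shared, against 1.5, and 0 genes were called in opposite directions. Among the 229 and 98 genes, 227 and 92 had the same sign with drug.

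**Figure D2:**
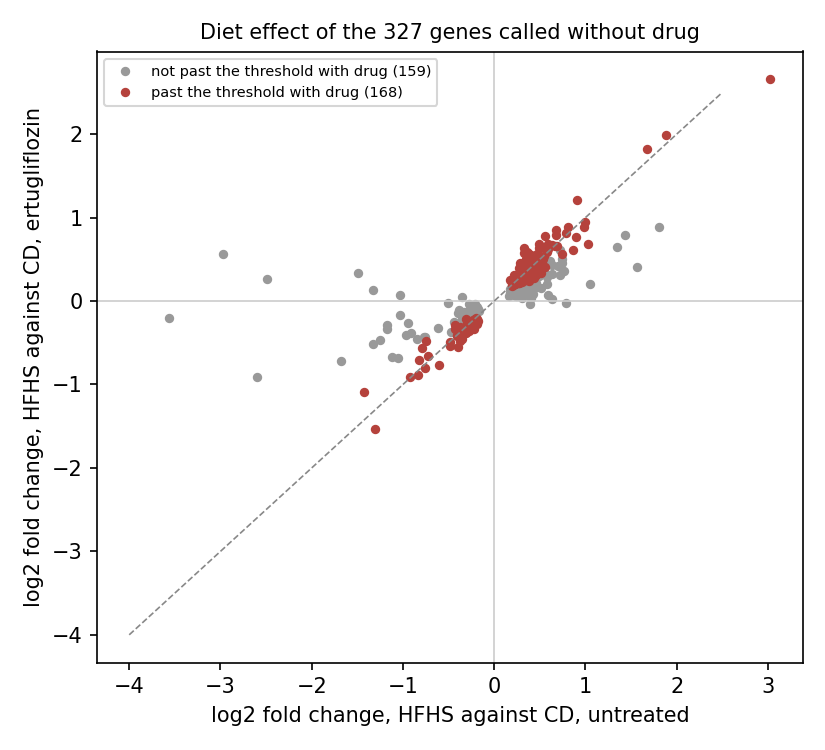
Log2 fold change of HFHS over CD in untreated animals (horizontal) and in ertugliflozin animals (vertical) for the 327 genes past the threshold without drug, one point per gene. The 168 genes also past the threshold with drug and the 159 that were not are drawn apart.

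A mean of the diet effects over both drug arms, chosen after the data were seen, used all 16 libraries. Chrna2 was higher on HFHS by 1.74 ± 0.11 (edgeR adjusted p = 4.73e-08), Acot2 by 0.84 ± 0.06, Tshz1 by 0.54 ± 0.04 and Fbxo21 by 0.47 ± 0.04, and Oxct1 changed by −0.40 ± 0.04 (edgeR adjusted p = 2.34e-06). Angptl4 passed in this comparison at 1.52 ± 0.34 (edgeR adjusted p = 0.014). In all, 1044 genes rose and 793 fell (edgeR, 1837 in total, 4205 at an unadjusted p under 0.05). Upper-quartile scaling gave 914 higher and 1021 lower. With valve and atrial scores as covariates 793 passed, and all 1837 kept their sign while the median error rose from 0.051 to 0.065. The 1837 were selected in the same libraries, so kept signs are no separate support. Mean scores per library were compared by exact two-sided permutation of diet labels within drug arms, in 4900 arrangements whose smallest p is 4.08e-04, and adjusted over 48 lists. Scores of 5 lists changed. Fatty acid oxidation was higher by 0.23 and PPAR targets by 0.523 (both exact p = 4.08e-04, adjusted p = 0.0098). Branched-chain amino acid catabolism differed by −0.142 (exact p = 8.16e-04, adjusted p = 0.0131), complexes III and IV by −0.104 and ATP synthase by −0.097 (both exact p = 0.00408, adjusted p = 0.0392). By camera with an estimated correlation only PPAR targets passed (adjusted p = 0.048), against 0.4 for fatty acid oxidation and 0.77 for each of the other 3 lists. Endothelial markers were higher in 17 of 20 (median 0.11, 3 risen, 7 risen adjusted over the list alone, adjusted p = 0.78 with an estimated correlation) and macrophage markers lower in 16 of 20 (median −0.18, 1 fallen, 0 adjusted over the list alone, adjusted p = 0.82 with an estimated correlation). Valve markers (median −1.1) and atrial markers (−0.33) were lower as well, each with 0 adjusted over the list alone and adjusted p = 0.82 with an estimated correlation. The difference for complex I was −0.084 and did not pass (exact p = 0.0143, adjusted p = 0.0762). Over all 74 respiratory chain members the difference went from −0.093 ± 0.0286 (SE) to −0.0591 ± 0.0234 after a correction for gene length and GC. In the plain 4 against 4 comparisons the smallest p such a test allows is 0.0286, and 0 of 48 lists passed after adjustment in any of them, against 5, 1, 4 and 7 at an unadjusted p under 0.05 for diet without drug, drug on CD, drug on HFHS and diet with drug. A list could pass there only if many lists reached that smallest p together. The lack of passing lists in these comparisons therefore decides nothing for or against a single list.

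The drug was then compared with no drug on the control diet, to ask what it does without the HFHS diet. Levels of 3 interferon-inducible GTPase genes rose, and no other gene passed. Iigp1 rose from 49.6 ± 4.6 to 90.5 ± 14.6 CPM (SD, n = 4 per group), a log2 fold change of 0.87 ± 0.12 (SE, edgeR adjusted p = 0.0202). Tgtp2 rose from 7.68 ± 1.17 to 15.1 ± 2.26, by 0.97 ± 0.14 (edgeR adjusted p = 0.0202), and Igtp from 19.2 ± 2.14 to 32.5 ± 5.02, by 0.76 ± 0.12 (edgeR adjusted p = 0.0283). Related genes had smaller or less certain differences that did not pass: Irgm2 at 0.67 ± 0.11 (edgeR adjusted p = 0.0693), the checkpoint ligand Cd274 at 0.52 ± 0.10, the activator of class I genes Nlrc5 at 0.82 ± 0.16, the peptide transporter Tap1 at 0.58 ± 0.12 and Gbp4 at 0.70 ± 0.14. The growth factor Fgf16 stood at 0.54 ± 0.11 and Ehhadh at 0.41 ± 0.09, also short of the threshold. Pdk4 was at 0.99 ± 0.24 (edgeR adjusted p = 0.648), Myh7 at −1.25 ± 0.49 and Col1a1 at −0.56 ± 0.21. Iigp1 (ENSMUSG00000054072) lies on chromosome 18 from 60376027 to 60392634, Tgtp2 (ENSMUSG00000078921) on chromosome 11 from 49057194 to 49064206 and Igtp (ENSMUSG00000078853) on chromosome 11 from 58199556 to 58207591 in GRCm38. Igtp overlaps Irgm2 on the same strand and Tgtp2 has the near copy Tgtp1, so their counts are uncertain.

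These 3 calls were fragile. Of 15841 genes 978 had an unadjusted p under 0.05, DESeq2 called 9 and limma-voom 3. Without CD untreated replicates 1, 2 or 4 or CD ertugliflozin replicate 2 the count was 0. It was 1 without CD ertugliflozin replicates 1 or 3, and 6 without replicate 4. It was 0 without CD untreated replicates 2 and 3 together and 0 with valve and atrial scores as covariates, where Iigp1 stood at 1.01, against 0.87 without them. Interferon response genes were higher in 23 of 28 (median 0.15, 1 risen, 3 risen adjusted over the list alone, camera adjusted p = 1.26e-06, adjusted p = 0.48 with an estimated correlation). Class II histocompatibility genes were higher in 8 of 8 (median 0.41, 0 adjusted over the list alone, adjusted p = 0.48 with an estimated correlation) and B and plasma cell markers in 12 of 14 (median 0.4, 0 adjusted over the list alone, adjusted p = 0.57 with an estimated correlation). Extracellular matrix genes were lower in 38 of 38 (median −0.31, 0 changed, 0 adjusted over the list alone, adjusted p = 0.41 with an estimated correlation), as were valve and cartilage markers in 10 of 10 (median −2, 0 changed over all genes, 8 fallen adjusted over the list alone, adjusted p = 0.23 with an estimated correlation). Fibroblast markers were lower with the matrix genes in 13 of 19 (median −0.15, 0 adjusted over the list alone, adjusted p = 0.52 with an estimated correlation). The matrix call ended with the covariates (median −0.051) and without CD untreated replicates 2 and 3 (0.0023). Fatty acid oxidation genes had a median of 0.071 (0 changed, 0 adjusted over the list alone, adjusted p = 0.48 with an estimated correlation), and their preset-correlation call ended without CD ertugliflozin replicate 4. Medians were 0.13 for PPAR targets (3 risen adjusted over the list alone, adjusted p = 0.23 with an estimated correlation) and 0.081 for complex I (0 adjusted over the list alone, adjusted p = 0.47 with an estimated correlation). They were 0.12 for branched-chain amino acid catabolism (2 risen adjusted over the list alone, adjusted p = 0.41 with an estimated correlation) and −0.31 for hypertrophy genes (0 adjusted over the list alone, adjusted p = 0.23 with an estimated correlation). Atrial cardiomyocyte markers were lower with the hypertrophy genes, in 11 of 13 (median −0.25, mean −1.3, 4 fallen adjusted over the list alone, adjusted p = 0.41 with an estimated correlation), with CD untreated replicate 1 at a score of 2.3. Camera called 20 of 48 lists, 11 higher and 9 lower, and 0 with an estimated correlation.

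The drug was also compared with no drug on the HFHS diet. The series title speaks of diabetes, but no measure of glucose was analysed here. No gene passed. Of the 10 genes with the smallest p, Ifi44 went from 10.7 ± 1.74 to 6.04 ± 1.26 CPM (SD, n = 4 per group), a log2 fold change of −0.82 ± 0.18 (edgeR adjusted p = 0.653). Oas2, an antiviral synthetase, went from 23.4 ± 5.03 to 14.5 ± 2.09, by −0.69 ± 0.15, and Ifi213 was at −0.67 ± 0.15 (edgeR adjusted p = 0.653 for both). Vsir, an immune checkpoint receptor, was at −0.38 ± 0.08, Sema4c at −0.35 ± 0.08, Cd38 at −0.48 ± 0.11, Sipa1 at −0.28 ± 0.06, Abcc4 at −0.31 ± 0.07 and Ddx58, a sensor of viral RNA, at −0.34 ± 0.08. Chrna2 was at 0.64 ± 0.14, in the direction of the diet effect. Pdk4 was at 0.35 ± 0.24, short of the threshold. Of 15841 genes edgeR called 0, with 637 at an unadjusted p under 0.05, and DESeq2, limma-voom and limma on the deposited rlog values called 0 each. On simulated counts of this comparison the edgeR test recovered 92.4% of 66 genes changed 2-fold and 68.7% of 67 changed 1.5-fold, but 26.9% of 67 given the smallest change. In those counts many genes changed at once and varied independently, so recovery in the real libraries may be lower.

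By list, interferon response genes were lower in 28 of 28 (median −0.46, 0 changed over all genes, 23 fallen adjusted over the list alone, camera adjusted p = 7.68e-33, adjusted p = 0.18 with an estimated correlation). Fatty acid oxidation genes were higher in 20 of 20 (median 0.14, 10 risen adjusted over the list alone, adjusted p = 0.18 with an estimated correlation), PPAR targets in 20 of 22 (median 0.12, 0 adjusted over the list alone, adjusted p = 0.18 with an estimated correlation), TCA cycle genes in 19 of 19 (median 0.075, 0 adjusted over the list alone, adjusted p = 0.46 with an estimated correlation) and complex I subunits in 36 of 36 (median 0.059, 0 adjusted over the list alone, adjusted p = 0.54 with an estimated correlation). Brown adipocyte markers were higher with them in 8 of 9 (median 0.092, 0 adjusted over the list alone, adjusted p = 0.18 with an estimated correlation). Matrix genes did not move as a list (20 higher and 18 lower, median 0.002, camera adjusted p = 0.82). Neutrophil markers were lower in 5 of 6 (median −0.41, 0 adjusted over the list alone, adjusted p = 0.44 with an estimated correlation). Erythroid markers were lower in 9 of 9 (median −0.41, 0 adjusted over the list alone, adjusted p = 0.18 with an estimated correlation) and macrophage markers in 18 of 20 (median −0.16, 0 adjusted over the list alone, adjusted p = 0.54 with an estimated correlation). Also lower were endothelial markers in 18 of 20 (median −0.098, 0 adjusted over the list alone, adjusted p = 0.54 with an estimated correlation), inflammatory and NF-kB genes in 19 of 23 (median −0.17, 0 adjusted over the list alone, adjusted p = 0.46 with an estimated correlation) and mesothelial markers in 7 of 8 (median −0.25, 2 fallen adjusted over the list alone, adjusted p = 0.18 with an estimated correlation). Valve and cartilage markers were higher in 10 of 10 (median 0.78, 0 adjusted over the list alone, adjusted p = 0.69 with an estimated correlation), a call that ended without HFHS untreated replicates 1 or 3 or HFHS ertugliflozin replicates 2 or 3. Camera called 21 of 48 lists, 10 higher and 11 lower, and 0 with an estimated correlation; fry called 0.

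**Figure D3:**
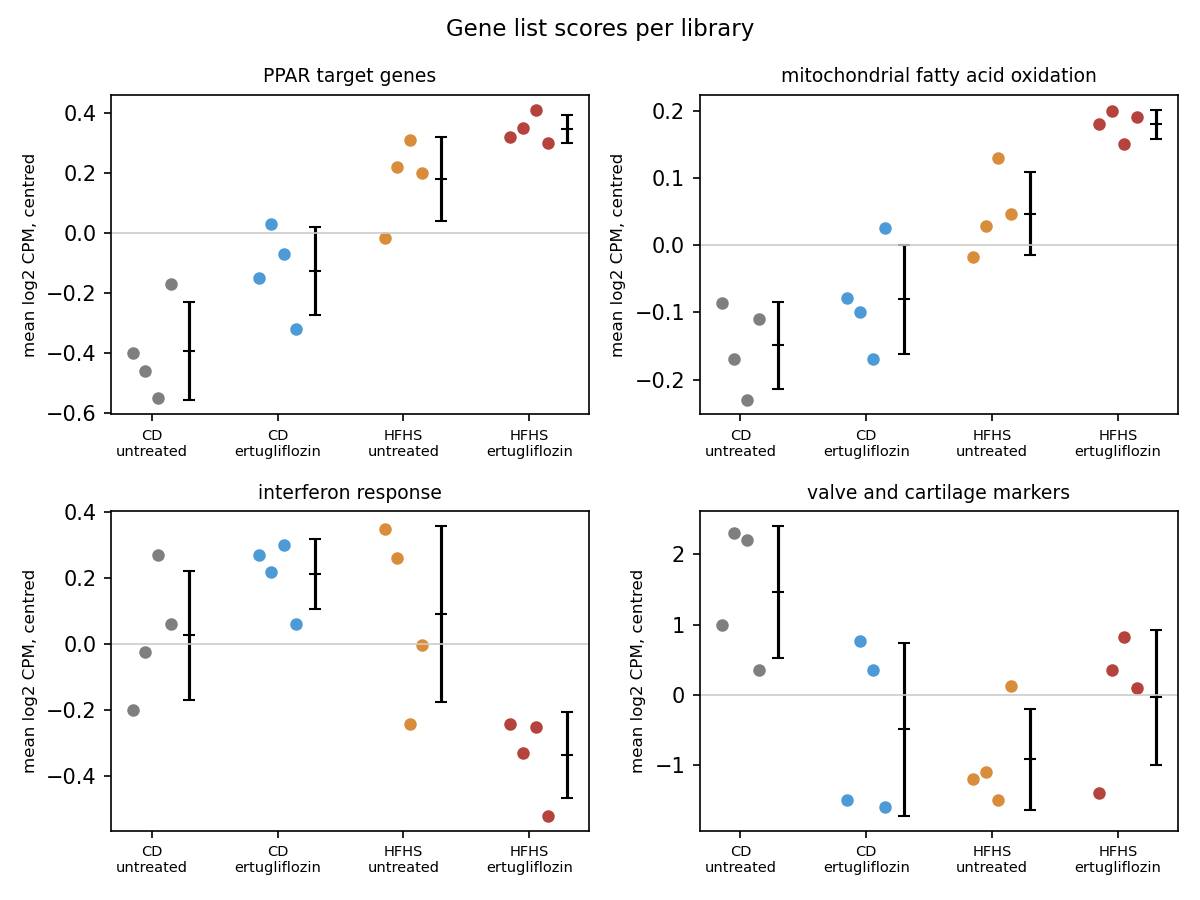
Mean score (log2, centred over all 16 libraries) of PPAR targets, fatty acid oxidation, interferon response and valve and cartilage markers in each library by group, with mean and SD of 4 libraries. The fatty acid oxidation score averaged −0.15, −0.08, 0.048 and 0.18 in CD untreated, CD ertugliflozin, HFHS untreated and HFHS ertugliflozin.

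Whether the drug's effect differed between diets was tested by the interaction. It shares the 4 CD ertugliflozin libraries with the drug comparison on CD and the diet comparison among treated animals. For interferon genes these results are therefore not independent of each other. Iigp1 averaged 49.6, 90.5, 44 and 32.8 CPM in CD untreated, CD ertugliflozin, HFHS untreated and HFHS ertugliflozin. The 3 GTPase genes that rose with drug on CD had lower estimates on HFHS: Iigp1 −0.42 ± 0.13, Tgtp2 −0.41 ± 0.16 and Igtp −0.37 ± 0.13, none past the threshold there. Their interactions were −1.29 ± 0.17, −1.38 ± 0.22 and −1.13 ± 0.17 (edgeR adjusted p = 0.0219 for each). Tap1 (−0.98 ± 0.17, edgeR adjusted p = 0.0809) and Gbp3 (−1.08 ± 0.19, edgeR adjusted p = 0.12) did not pass. Interferon response genes were lower in 28 of 28 (median −0.58, 1 fallen, 21 fallen adjusted over the list alone, camera adjusted p = 3.82e-34, adjusted p = 0.21 with an estimated correlation). The exact permutation test of the interferon score gave a difference of −0.614 (p = 0.0049, adjusted p = 0.216 over 48 lists). The medians of matrix genes (0.29, 0 changed, 0 adjusted over the list alone, adjusted p = 0.6 with an estimated correlation) and valve markers (3.2, 0 changed, 10 risen adjusted over the list alone, adjusted p = 0.45 with an estimated correlation) were above 0. So were those of atrial (0.33), conduction (0.55) and fibroblast markers (0.15), with adjusted p of 0.7, 0.56 and 0.82 with an estimated correlation. Lower with the interferon genes were class II genes (−0.66), macrophage (−0.19), B and plasma cell (−0.61), erythroid (−0.53) and endothelial markers (−0.18), with adjusted p of 0.6, 0.7, 0.7, 0.45 and 0.6 with an estimated correlation. Of these 8 lists only the conduction markers had members past the threshold adjusted over the list alone, 2 risen. By edgeR 3 genes passed and 676 had an unadjusted p under 0.05, against 18 by DESeq2 and 6 without the count filter. The count was 0 without CD untreated replicates 1, 2 or 4, without HFHS untreated replicates 1, 2 or 4 and without HFHS ertugliflozin replicates 2, 3 or 4, 7 without CD ertugliflozin replicate 4 and 18 without HFHS untreated replicate 3. It was 0 without CD untreated replicates 2 and 3. It was 0 with valve and atrial covariates, where the interaction of the interferon score was −0.656 ± 0.243, against −0.614 ± 0.185 (SE) without them.

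Averaged over both diets, the drug changed 0 of 15841 genes by edgeR, with 882 at an unadjusted p under 0.05, 4 by DESeq2, 0 by limma-voom and 1 without HFHS untreated replicate 1. The 5 genes of smallest p were Chrna2 (0.57 ± 0.11) and Fgf16 (0.39 ± 0.08), with an edgeR adjusted p of 0.795, and Dapk2 (−0.35 ± 0.08), Oas2 (−0.49 ± 0.11) and Hsdl2 (0.13 ± 0.03), with 0.848. PPAR targets were higher in 22 of 22 (median 0.13, 7 risen adjusted over the list alone, adjusted p = 0.16 with an estimated correlation) and fatty acid oxidation genes in 20 of 20 (median 0.099, 11 risen adjusted over the list alone, adjusted p = 0.26 with an estimated correlation). Lower with drug were heat shock genes in 19 of 19 (median −0.12, 0 adjusted over the list alone, adjusted p = 0.29 with an estimated correlation), immediate early genes in 20 of 22 (median −0.19, 2 fallen adjusted over the list alone, adjusted p = 0.36 with an estimated correlation) and matrix genes in 38 of 38 (median −0.15, 0 adjusted over the list alone, adjusted p = 0.5 with an estimated correlation). The matrix difference came from CD, with a median of −0.31 there and 0.002 on HFHS. Valve markers were lower with them in 9 of 10 (median −0.37, adjusted p = 0.5 with an estimated correlation), atrial markers in 11 of 13 (−0.11, adjusted p = 0.5 with an estimated correlation) and conduction markers in 11 of 11 (−0.24, adjusted p = 0.29 with an estimated correlation). Mesothelial (−0.2), erythroid (−0.14) and lymphatic endothelial markers (−0.13) were also lower, with adjusted p of 0.29, 0.5 and 0.5 with an estimated correlation, and each of these 6 lists had 0 members changed adjusted over the list alone. Macrophage markers (16 of 20, median −0.056) and fibroblast markers (12 of 19, median −0.066) were lower too, each with 0 adjusted over the list alone and adjusted p = 0.57 with an estimated correlation. In the exact permutation of library scores, PPAR targets differed by 0.216 and fatty acid oxidation by 0.102 (p = 0.00735 and adjusted p = 0.118 for both). Camera called 25 of 48 lists, 8 higher and 17 lower, and 0 with an estimated correlation. Across the 15841 genes, which are not independent replicates, the drug effects on CD and HFHS, which share no library, had Pearson r = −0.0754 and Spearman rho = 0.0459, and 43 of 100 draws with drug labels reassigned within diets gave an r as large in size (range −0.266 to 0.22). The value was −0.232 without HFHS untreated replicate 4.

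The last comparison asked whether the drug moves HFHS hearts against the diet effect. Across genes the diet effect without drug and the drug effect on HFHS had r = −0.371 and rho = −0.31, but both use the HFHS untreated libraries with opposite sign. Simulated groups with no change gave a mean r of −0.51 (−0.564 to −0.447). The covariance was −0.0213, against −0.0212 simulated, a difference of −1.56e-04. With the 4 HFHS untreated libraries divided 2 and 2, the mean r over 6 divisions was −0.0464 (−0.216 to 0.0783). Leaving out HFHS untreated replicate 4 gave r = −0.592. No simulated value is given for that smaller group, so this r cannot be read against the range above.

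A survey of 679 Reactome pathways found 193 past the threshold for diet without drug (68 higher, 125 lower), 81 for drug on CD (58 higher, 23 lower) and 16 for drug on HFHS (11 higher, 5 lower), with 0 in each under an estimated correlation. For diet without drug the top pathway was mitochondrial translation termination (81 genes, median −0.087, adjusted p = 0.31 with an estimated correlation). For drug on CD, respiratory electron transport (65 genes, median 0.08) was higher and collagen formation (60 genes, median −0.22) lower, each with adjusted p = 0.78 with an estimated correlation. For drug on HFHS, respiratory electron transport (median 0.06) was higher and interferon gamma signaling (72 genes, median −0.18) lower, each with adjusted p = 0.98 with an estimated correlation.

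**Figure D4:**
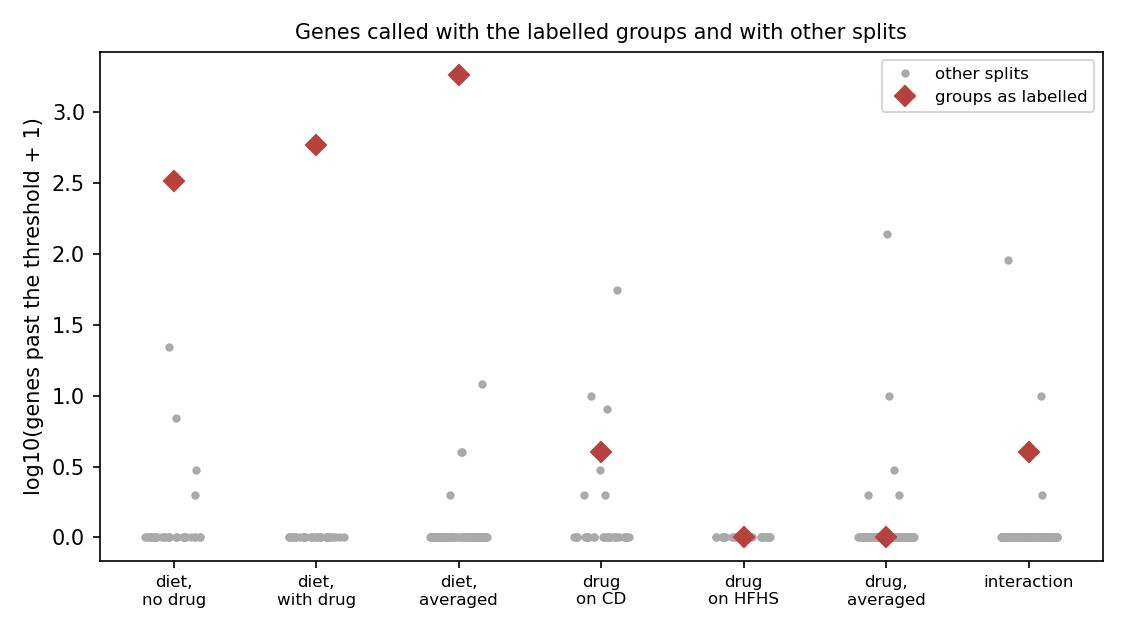
Number of genes past the threshold, drawn as log10 of the number plus 1, for the labelled groups and for other splits of the same libraries into groups of equal size. Diet without drug gave 327 genes against at most 21 in the other splits, and drug on CD gave 3 against at most 55.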

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

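Tests chosen only after the result was seen were those of gene length and GC, of the cardiomyocyte share, and of valve and atrial tissue; the splits of the libraries and the tests of macrophage and fibroblast shares were set out before their results were seen.

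The 3 counts of genes that changed with diet stood above those of every other split tried. With 35 splits, 1 of 35 is the strongest result possible. The averaged diet effect is the mean of both plain diet comparisons, so the counts are not independent of each other. Diet without drug gave 327 genes, as many as in 1 of the 35 splits of its 8 libraries, the labelled one, with 21 as the highest of the others. Diet with drug gave 584 (1 of 35, highest other 0) and the averaged diet effect 1837 (1 of 100 drawn splits, highest other 11). The interaction gave 3 (3 of 100, highest other 89), few enough splits to pass the test as set out. That margin rests on 100 draws and on calls that ended without any of several single libraries, so chance is not taken as excluded. Chance cannot be excluded for the drug on CD, where 3 genes were reached in 4 of 35 splits with up to 55. For the drug on HFHS (35 of 35, highest other 0) and the averaged drug effect (100 of 100, highest other 136) the count was 0, which every split reaches, so the splits test nothing there. The split with 55 genes set replicates 2 and 3 of both CD groups against replicates 1 and 4, which points to a structure of these libraries other than drug. Macrophage scores were 0.13 to 0.37 in the former and −0.13 to −0.059 in the latter. Macrophage markers were not alone in this. Scores also parted for neutrophil markers (0.14 to 0.48 against −0.38 to −0.11), class II genes (0.17 to 0.96 against −0.21 to 0.12) and matrix genes (−0.018 to 0.64 against −0.69 to −0.068). Those of other lists overlapped, such as interferon response (−0.022 to 0.3 against −0.2 to 0.27). Splits with 89 genes for the interaction and 136 for the averaged drug effect likewise point to structure beyond the labels, and the 3 interaction genes do not stand clear of it.

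Counts of lists called at a preset correlation do not stand above other splits. Diet without drug called 14 lists (21 of 35 splits as many, highest other 26), drug on CD 20 (12 of 35, 31), drug on HFHS 21 (3 of 35, 27), diet with drug 15 (19 of 35, 24), the interaction 16 (42 of 100, 35), the averaged drug effect 25 (8 of 100, 31) and the averaged diet effect 18 (19 of 100, 27). Reactome counts were 193 for diet without drug (2 of 35, highest other 250), 81 for drug on CD (4 of 35, 118) and 16 for drug on HFHS (27 of 35, 133), so chance cannot be excluded for any of these counts.

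Genes that differ between diets in their response to the drug form the first pattern weighed. Interactions were −1.29 for Iigp1, −1.38 for Tgtp2 and −1.13 for Igtp, with a median of −0.58 over the interferon list. The interaction of the interferon score, −0.614 ± 0.185 (SE), stayed at −0.555 ± 0.193 with the macrophage score as a covariate and at −0.656 ± 0.243 with valve and atrial scores, which argues against either as the whole cause. An effect of the drug that depends on diet stays open as a hypothesis, because the calls end without any of several single libraries and the list's adjusted p is 0.21 with an estimated correlation.

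Matrix genes that were lower with drug on CD (median of the interaction 0.29) form the second. Valve markers moved with them (interaction 3.2). The difference of the matrix score on CD, −0.518 ± 0.231 (SE), became 0.0432 ± 0.17 with the valve score as a covariate. A different amount of valve tissue between the samples of both CD groups is therefore a candidate explanation. Valve scores of replicates 1 to 4 were 1, 2.3, 2.2 and 0.36 in CD untreated and −1.5, 0.77, 0.36 and −1.6 in CD ertugliflozin. In both groups replicates 2 and 3 stood above 1 and 4, in the matrix score too. With the fibroblast score it was −0.416 ± 0.207, which leaves a share of fibroblasts open, and an effect of the drug on matrix genes cannot be told apart from it at this n.

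Respiratory chain subunits lower on HFHS form the third. Over 74 members the difference was −0.0872 ± 0.0404 (SE) without drug and −0.093 ± 0.0286 averaged, and it became −0.0563 ± 0.0331 and −0.0591 ± 0.0234 after a correction for gene length and GC, so such a trend cannot be told apart from an effect of diet, because the difference became smaller but did not vanish. A lower share of cardiomyocytes would raise the markers of other cell types alike only if those types kept their proportions to each other. The endothelial minus macrophage score differed between diets by 0.255 (exact permutation p = 0.00327, 4900 arrangements). This pair of lists was chosen after the result was seen, and the p is not adjusted for that choice. It does not show on its own that these types moved apart. The test cannot decide on the share, since more endothelial cells would lower it too. Averaged over drug arms, sarcomere genes were lower in 17 of 22 (median −0.11), endothelial markers higher in 17 of 20 and macrophage markers lower in 16 of 20. An effect of diet was not tested apart from these.

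In 14 of 308 groups of 4 libraries 1 library stood apart from the other 3, by Dixon's ratio. The ratio picks out about 1 in 20 groups by chance, here 15.4, so these are no more than chance gives. The ratios were 0.904 for Dysf in HFHS untreated (replicate 1) and 0.888 in HFHS ertugliflozin (replicate 4), 0.899 for Cilp2 in HFHS untreated (replicate 4), 0.926 for Etfdh in HFHS ertugliflozin (replicate 2), 0.833 for Acadsb and 0.874 for Sema4c in HFHS ertugliflozin (replicate 3), 0.84 for Angptl4 and 0.884 for Gbp3 in CD ertugliflozin (replicate 4), 0.834 for Ehhadh (replicate 2) and 0.846 for Mthfd2 (replicate 3) in CD ertugliflozin. For scores they were 0.879 for atrial markers in HFHS untreated (replicate 4), 0.871 for immediate early genes in HFHS untreated (replicate 3), 0.861 for endothelial markers in HFHS ertugliflozin (replicate 3) and 0.83 for sarcomere genes in CD untreated (replicate 1).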

How the results depend on the processing

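Settings chosen after the result was seen were the valve and atrial covariates, the gene length and GC correction and the fits without CD untreated replicates 2 and 3, and the averaged diet effect is itself such a choice. For changed counts the cause was not tested unless stated. RLE, upper-quartile scaling, the stricter filter, limma on the deposited log2 values and the length and GC correction kept each count of genes within 1.5 times. DESeq2 gave 593 genes for diet without drug, 9 for drug on CD, 891 for diet with drug, 18 for the interaction and 4 for the averaged drug effect. Limma-voom with sample weights gave 743 for diet without drug. A fit of only the groups compared, which has fewer samples, gave 136 for diet without drug and 1 for drug on CD, and no filter gave 6 for the interaction. The covariates gave 0 for diet without drug, drug on CD and the interaction and 793 for the averaged diet effect. For diet without drug 326 of the 327 genes kept their sign, for the averaged diet effect all 1837 did, and errors grew in both. Both sets of genes were selected in the same libraries, so kept signs are no separate support. Without CD untreated replicates 2 and 3, a fit with fewer samples, the counts were 97 for diet without drug, 0 for drug on CD and 0 for the interaction.

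Leaving out each library in turn gave 133 to 846 genes for diet without drug, 0 to 6 for drug on CD, 0 to 0 for drug on HFHS, 287 to 470 for diet with drug, 0 to 18 for the interaction, 0 to 1 for the averaged drug effect and 1372 to 2530 for the averaged diet effect. Lists called ranged from 13 to 21, 18 to 26, 18 to 25, 14 to 18, 11 to 17, 18 to 27 and 15 to 21 in the same order. The correlation of the drug effects ranged from −0.232 to −0.0101 and that of the diet effect with the drug effect on HFHS from −0.592 to −0.286. The latter was −0.304 under the stricter filter and −0.0464 with the HFHS untreated libraries divided. Its values with a library left out have no simulated values of their own beside them.

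With an estimated correlation the lists called were 1 for diet without drug, 1 for the averaged diet effect and 0 for the other 5 contrasts, and 0 Reactome pathways passed. Fry called 2 for diet without drug, 4 for diet with drug and 6 for the averaged diet effect. It called 0 for drug on CD, drug on HFHS, the interaction and the averaged drug effect. The covariates gave 23 lists for diet without drug and 12 for drug on CD, and leaving out CD untreated replicates 2 and 3 gave 23 and 10. The covariates turned the sign of matrix genes in the interaction (−0.15) and of Cilp2 for diet without drug (0.552), and took the valve markers to −0.089 for diet without drug, 0.089 for drug on CD, −0.033 for drug on HFHS and 0.077 for the interaction. The valve values follow from construction, since these genes make up the covariate.

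The same replicate number does not pair the libraries across all groups: of 24 same-number pairs 6 correlated above 0.1 (−0.24 to 0.31), and 2 samples correlated best with their own number in every other group. The numbers are not free of structure, however. CD untreated replicates 1 and 4 correlated best with CD ertugliflozin replicates 1 and 4. CD untreated replicates 2 and 3 correlated best with CD ertugliflozin replicates 3 and 2. With the replicate block edgeR called 329, 3, 0, 550, 2, 1 and 1796 genes in the order above. Depth limits single genes below about 1 CPM. Slc5a2, at 0 to 3 counts per library, was too low to test, and these counts do not show that it is expressed here.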

Other observations

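The tests of the interferon parts and of library scores were chosen after the result was seen; the camera and fry tests of lists were planned.

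Some lists of immune and blood cell genes passed with diet among treated animals at the preset correlation, and others did not. All 8 tested class II histocompatibility genes were lower on HFHS ertugliflozin than on CD ertugliflozin (median log2 fold change −0.94, 1 fallen, 7 fallen adjusted over the list alone, camera adjusted p = 8.84e-06, adjusted p = 0.66 with an estimated correlation). These genes present antigen to helper T cells. Macrophage markers were lower in 19 of 20 (median −0.27, 0 changed, 7 fallen adjusted over the list alone, adjusted p = 0.73 with an estimated correlation) and erythroid markers in 9 of 9 (median −0.33, 0 adjusted over the list alone, adjusted p = 0.66 with an estimated correlation). Lists of inflammatory and NF-kB genes, complement genes, neutrophil markers and B and plasma cell markers did not pass (camera adjusted p = 0.748, 0.146, 0.629 and 0.781). Averaged over drug arms, the class II score differed by −0.543 and did not pass (exact permutation p = 0.0143, adjusted p = 0.0762), and the hypoxia score by 0.107 (exact permutation p = 0.00898, adjusted p = 0.0672). On CD the drug went with lower conduction system markers in 11 of 11 (median −0.59, 2 fallen adjusted over the list alone, adjusted p = 0.23 with an estimated correlation), with atrial markers lower in 11 of 13 and CD untreated replicate 1 highest in both scores (1.1 and 2.3), and with lower heat shock genes (median −0.13, adjusted p = 0.41 with an estimated correlation) and immediate early genes (median −0.32, adjusted p = 0.41 with an estimated correlation), the latter sensitive to how fast tissue is frozen.

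A hypothesis is that the drug moves interferon-gamma-type genes on CD and type I interferon-type genes on HFHS. Each part had 20 genes, of which 8 and 18 were in the interferon list. By exact permutation the gamma-type score differed by 0.52 on CD (p = 0.0286, the smallest possible, adjusted p = 0.0571 over 4 tests) and by −0.31 on HFHS (adjusted p = 0.152). By the same exact permutation the type I score differed by 0.12 on CD (adjusted p = 0.486) and by −0.47 on HFHS (p = 0.0286, adjusted p = 0.0571). With 70 arrangements, 2 tests at the smallest p give no adjusted p below 0.0571, so these tests could not have passed for the 2 changes the hypothesis names. They decide nothing for or against it, and the parts were drawn up after the named genes had been seen.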
